A study of Homo sapiens with 4 samples.

How the data were processed

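RNA was measured by sequencing in HEK293T cells, a human embryonic kidney line, in which PBRM1 had been disrupted with CRISPR. Per the labels, the cells were transfected for 48 h with a plasmid for GFP-tagged PBRM1, either the unaltered protein (WT) or 1 of 3 mutants named for changes in its BAH (bromo-adjacent homology) domains: P1048R, T1202K and C1233W. There was 1 library per construct, 4 libraries in all, so no difference in the series has a replicate check. Total RNA was isolated with TRIzol, cleaned on columns and made into libraries with a stranded Qiagen kit, per the labels' protocols; whether ribosomal RNA was depleted or polyadenylated RNA selected is not given in the sources used here.

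The deposited values were whole-number read counts per gene, 1 column per library, with no normalization by the authors. Trim Galore, HISAT2, featureCounts and the human build hg38 are named in the submitters' processing notes, without versions; the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. All 58735 gene identifiers in the table matched GENCODE release 29, and 58422 had the same symbol there. Coordinates, GC content and transcript lengths were taken from that release (GRCh38), whereas biotypes came with the deposited counts. With the strand setting unknown, counts of antisense and overlapping genes are uncertain, and so are counts of pseudogenes, near-identical paralogs and nuclear copies of mitochondrial sequence. A library from cells without a plasmid was not analysed here.

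Total counts were 10246250 for WT, 11205322 for P1048R, 10993748 for T1202K and 10348552 for C1233W. A floor of 3 reads corresponded to 0.321, 0.251, 0.265 and 0.290 CPM in the same order, where CPM is the usual rate of counts relative to the TMM-scaled library size. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules and no interval here contains variation between cultures. The 95% intervals of single levels were exact Poisson intervals, and those of ratios came from Clopper-Pearson intervals of the share of reads in 1 of the 2 libraries.

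Library sizes were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 0.912 for WT, 1.07 for P1048R, 1.03 for T1202K and 0.999 for C1233W. The 16262 genes with at least 1 CPM in at least 1 library were compared. For each pair of libraries, the log2 ratio was taken after adding 0.5 to each count. A gene passed the size rule when this ratio was at least 1 in size (2-fold) and its 95% counting interval excluded 0. A gene stood apart in 1 library alone when it passed the rule against each of the other 3, in the same direction. Where a library held 0 reads of a gene, the ratio is given as a lower bound, computed against the floor of 3 reads per library. No p-value was made from the pairwise comparisons, because genes are not replicates.

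A set of 40 gene lists was fixed before the data were examined, and 38 of them had at least 5 measured members. They covered chromatin (PBAF and BAF subunits, Polycomb and H3K27 regulators, HOX genes, cohesin and condensin, replication-dependent histones) and stress (p53 targets, hypoxia and HIF targets, heat shock response, unfolded protein response, ATF4 and amino acid response, NRF2 targets, metallothioneins, immediate early genes, apoptosis regulators). Metabolism was covered by glycolysis, cholesterol synthesis, nuclear oxidative phosphorylation genes, mitochondrially encoded genes (ribosomal RNAs included), and autophagy and lysosome. Signalling and immune lists held interferon-stimulated genes, the NF-kB and inflammatory response, and TGF-beta, Wnt and Notch targets. Growth lists held mitosis and spindle, DNA replication, DNA repair, ribosomal protein, ribosome biogenesis, spliceosome, and small nuclear and structural RNA genes. Structure was covered by tubulins, actin and SRF targets, cell adhesion and junctions, and extracellular matrix. Markers of kidney epithelium, neurons, blood cells, fibroblasts and endothelium, and keratinocytes and carcinoma lines completed the set.

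For each list, the median log2 ratio of its measured members is given relative to the median of all 16262 genes. Its percentile was taken among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when that percentile was under 1 or over 99. If list members were unrelated genes, 0.76 of the 38 lists would do so by chance in each comparison. Members of a real list can vary together between cultures, so the number that would stand apart without any effect of a construct is not known. Because of the matching, a list of highly expressed genes can stand apart upward with a median at or slightly below that of all genes. The percentiles describe these 4 libraries and are not p-values.

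Genes are named by a rule fixed at the same time. For each mutant against WT, and for WT alone, it took the 12 higher and 12 lower genes whose interval bound nearest to 0 was largest, leaving clone names and numbered non-coding genes unnamed. It added PBRM1 and up to 4 members of each list with the largest bounds. The few genes named outside the rule are marked in the text.

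The mutant ratios share 1 WT library. Unchanged libraries sharing 1 control were therefore simulated 100 times with counting error alone, and 100 times with the spread of all 4 libraries taken as 1 group. The size rule was tested on data simulated with counting error alone, modelled on C1233W against WT over 16262 genes. It called 0% of genes changed 1.5-fold, 38% of those changed 2-fold, 98% of those changed 4-fold and 0.747% of unchanged genes. No variation between cultures was simulated there, so the last share is not the rate of false calls in the real libraries. In data simulated for P1048R against WT, 95.3% of the intervals of the 13387 unchanged genes with a mean of at least 20 reads held 0; genes with fewer reads were not part of that check.

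Alternatives were DESeq2 1.42.0 size factors, total-count scaling, no filter on low counts, a minimum of 5 CPM, counts thinned to the smallest library, a 1.5-fold threshold, and a counting bound of at least 1.5-fold. A further alternative was edgeR's quasi-likelihood test of 1 library against the other 3 taken as 1 group, with Benjamini-Hochberg adjustment at 0.05; its spread is that between 3 different constructs, and the lone library is assumed to vary like them. Chosen after seeing the data were removal of each library's trend with GC content and transcript length in 50 bins, TMM scaling without PBRM1 and mitochondrial genes, total counts without PBRM1, and leaving out the WT library. Further computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.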

Results

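PBRM1 (BAF180) is a subunit of the PBAF chromatin remodelling complex, and carries a row of bromodomains followed by BAH domains. The series asks how the transcriptome of PBRM1-disrupted HEK293T cells differs 48 h after re-expression of WT PBRM1 or of a BAH domain mutant. The 4 libraries, 1 per construct, held between 10246250 and 11205322 counted reads, and reads fell on 25670 to 26718 genes. With 1 library each, the differences below are differences between libraries, without a replicate check.

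PBRM1 itself, on the minus strand of chromosome 3 from 52545352 to 52685917 (ENSG00000163939), was abundant in every library. Its level was 22768 CPM in WT (22671 to 22865), 8805 in P1048R (8752 to 8859), 15262 in T1202K (15190 to 15334) and 60509 in C1233W (60359 to 60659). These were 2.08%, 0.938%, 1.57% and 6.04% of all counted reads. In CPM, WT thus held 2.59 times the PBRM1 level of P1048R and 1.49 times that of T1202K, whereas C1233W held 2.66 times the WT level and 6.87 times that of P1048R. Gene counts do not separate plasmid transcripts from those of the edited locus, so the values check transcription of the gene and neither the editing nor the mutation.

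**Figure D1:**
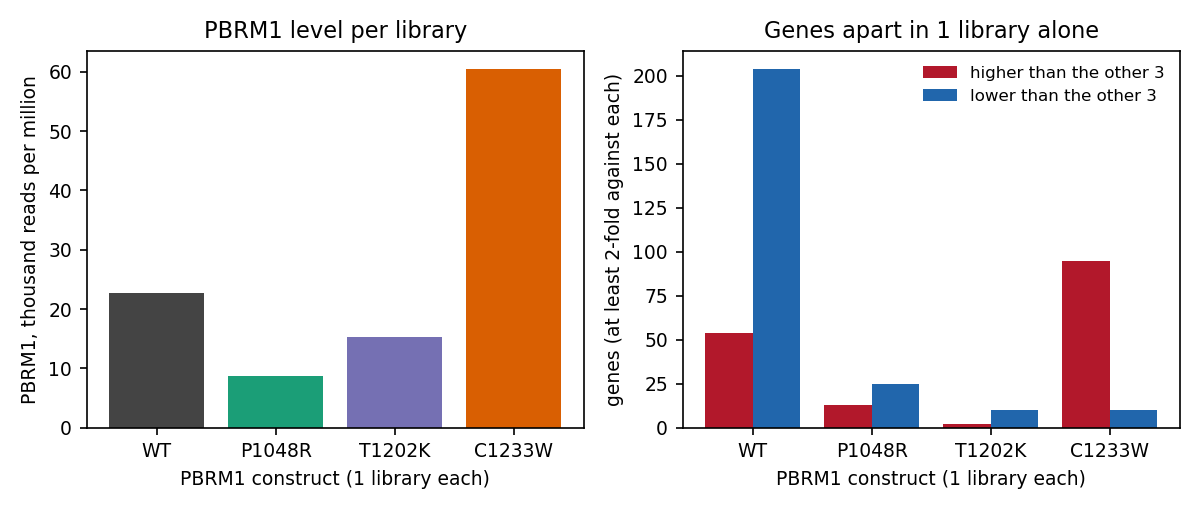
Left, PBRM1 level per library (TMM-scaled), with 1 bar per construct: 60509 CPM in C1233W and 8805 CPM in P1048R. Right, the number of genes at least 2-fold higher (red) or lower (blue) in 1 library than in each of the other 3: 258 in all for WT, 38 for P1048R, 12 for T1202K and 105 for C1233W.

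In P1048R, COL5A3, a collagen V chain (chromosome 19, 9959561 to 10010471), stood at 15.4 CPM against 0.535 in WT, a log2 ratio of 4.71 (3.60 to 6.49). PHF21B (chromosome 22, 44881162 to 45009999) was higher by 2.53 (2.21 to 2.88), reaching 52.9 CPM. CELSR3, an atypical cadherin of axon guidance, was at 60.1 CPM against 15.0 in WT (interval of the log2 ratio 1.74 to 2.28). RIMS2, a presynaptic scaffold protein, was higher by 2.22 (1.73 to 2.77), and GABBR2, a GABA-B receptor subunit, by 2.34 (1.80 to 2.97). DUSP8, a MAP kinase phosphatase, was higher by 2.07 (1.73 to 2.44). On the lower side were the nuclear non-coding RNA MALAT1 (−1.58, −1.70 to −1.47), the GTPase gene RAB13 (−1.61, −1.81 to −1.42) and PALM3 (−1.61, −1.90 to −1.34).

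Heat shock, mitochondrial, matrix and adhesion genes were among the lists that stood apart downward in P1048R. The heat shock list had a median of −0.76, with 4 of 19 members passing the size rule, all lower; the inducible chaperones HSPA6 (−2.07) and HSPA1A (−1.08) were among them. Mitochondrially encoded genes had a median of −0.86, with 5 of 15 members lower, including MT-ATP8 (−1.34) and MT-ATP6 (−1.25). Extracellular matrix genes (median −0.46) and cell adhesion genes (−0.34) also stood apart, with 2 of 32 and 1 of 31 members passing the rule, all lower; COL3A1 (−1.02) and COL6A3 (−1.25) were the matrix genes and E-cadherin, CDH1, the adhesion gene (−1.20). Fibroblast and endothelial markers, 7 measured, which share COL3A1, COL1A1 and LUM with the matrix list, had the lowest median of the lists apart in P1048R, −0.88, with KDR at −1.82 and CLDN5 in the other direction, at 1.93 CPM against 0.642. Glycolysis (−0.42), cholesterol synthesis (−0.29), nuclear oxidative phosphorylation (−0.25) and HOX genes (−0.21) stood apart downward, though HOXD3 (−1.86) was the only one of their members to pass the rule.

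Replication-dependent histones had the highest list median in P1048R, 0.82, with 3 of 10 members higher. These were HIST2H4A (2.74), HIST1H4H (1.66) and HIST1H2AC (1.26), of which HIST2H4A is uncertain because a near-identical copy shares its reads. The p53 target list (0.33) stood apart with 1 member higher, PLK3 (1.41), and 1 lower, TP53I3 (−1.12). The ATF4 and amino acid response list (0.24) had 4 of 27 members higher, among them the cystine transporter SLC7A11 (40.7 CPM against 16.5 in WT) and the pseudokinase gene TRIB3 (log2 1.40). DNA repair genes (0.22) stood apart without any member passing the rule.

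In total 1219 of 16262 genes passed the size rule in P1048R against WT, 728 higher and 491 lower, and 13 of 38 lists stood apart. On total-count scaling, which moves the all-gene median to 0.18, the split became 1253 higher and 231 lower, and HSPA1A, COL3A1, COL6A3, CDH1 and TP53I3 no longer passed. COL3A1 was also under 2-fold with DESeq2 size factors (−0.98) and with thinned counts (−0.99). With the GC and length trend removed, the call for nuclear oxidative phosphorylation was lost (percentile 7.67). Under the same setting MT-ATP8 (−0.93), MT-ND5 (−0.90) and MT-ND6 (−0.999) were under 2-fold, whereas MT-ND2 (−1.06) and MT-ATP6 (−1.01) were still past it.

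Some of the genes named for P1048R, such as PHF21B, COL5A3, DUSP8 and MALAT1, also differed between T1202K and WT. PHF21B was higher by 2.09 (1.76 to 2.45), COL5A3 stood at 6.18 CPM (interval of the log2 ratio 2.24 to 5.20), and higher too were DUSP8, by 1.92 (1.58 to 2.30), and PBX4, a TALE homeobox gene, by 2.11 (1.52 to 2.80). KRTAP5-1, of a keratin-associated family of similar genes and so uncertain, had 0 reads in WT and was at least 6.88-fold higher in T1202K. MALAT1 was lower by −1.85 (−1.98 to −1.72) and HMGN5, a nucleosome-binding protein gene on chromosome X, by −1.51 (−1.63 to −1.40). NEAT1, the architectural RNA of paraspeckles, was lower by −1.33 (−1.44 to −1.22).

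Among lists, mitochondrially encoded genes (median −0.78, 4 of 15 lower) and the heat shock list (−0.50, 1 of 19 lower) lay lowest among those that stood apart in T1202K, followed by extracellular matrix (−0.31), mitosis and spindle genes (−0.27), HOX genes (−0.26) and cell adhesion (−0.24). Interferon-stimulated genes had a median of −0.26 with 5 of 25 members lower, including SAMD9 (−1.12), IFIT1 (−1.36), IFIT3 (−1.47) and IFI44L (−1.95). The same list had 5 members lower in P1048R, though its median of −0.15 did not stand apart there. Upward stood the ATF4 and amino acid response (0.47, 3 of 27 higher), immediate early genes (0.33, none higher and 1 lower), p53 targets (0.29), DNA repair (0.11) and DNA replication genes (0.08). The licensing factor gene CDT1, at 179 CPM against 71.4 in WT (log2 1.33, 1.20 to 1.46), was the single replication gene to pass the rule.

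In all, 838 genes passed the rule in T1202K against WT, 479 higher and 359 lower; on total-count scaling, with an all-gene median of 0.17, the split was 806 and 221. The interferon call was lost without a filter (percentile 2.17) and with a minimum of 5 CPM (1.13), the replication call with the GC and length trend removed (95.8), where CDT1 was at 0.93 and SAMD9 no longer passed (on total counts it was at −0.94), and the repair call under both other filters. The 4 mitochondrially encoded genes that had passed were also under 2-fold with that trend removed: MT-ND2 (−0.98), MT-ATP6 (−0.94), MT-ATP8 (−0.94) and MT-ND6 (−0.92).

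C1233W was marked by genes of the amino acid and hypoxia responses. SLC7A11 (chromosome 4, 138164097 to 138242349) stood at 112 CPM against 16.5 in WT, a log2 ratio of 2.77 (2.53 to 3.02). DDIT4 (REDD1), an inhibitor of mTORC1 signalling on chromosome 10 (72273920 to 72276036), was higher by 2.60 (2.27 to 2.95), the asparagine synthetase gene ASNS by 2.53 (1.93 to 3.24), and CHAC1, a glutathione-degrading enzyme, by 2.48 (1.92 to 3.13). JDP2, an AP-1 family repressor, was higher by 2.22 (1.66 to 2.87), and IL11, at 2 reads in WT, by 3.64 (1.98 to 7.04). Of the 19 heat shock response genes measured, 4 were lower: HSPA1A by −2.17 (−2.22 to −2.11), HSPA1B by −1.67 (−1.74 to −1.59), HSPA8 by −1.43 (−1.48 to −1.38) and DNAJA1 by −1.17 (−1.25 to −1.10). HSPA1A and HSPA1B lie next to each other on chromosome 6 and are nearly identical, so reads may be divided between them, and HSPA6 likewise has a close pseudogene copy. MAT2A, which makes S-adenosylmethionine, was lower by −1.16 (−1.26 to −1.07).

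The ATF4 and amino acid response list had a median of 0.92 in C1233W against WT, above all matched random lists, with 13 of 27 members higher and 1 lower. The hypoxia list had a median of 0.55 with 5 of 26 members higher, among them ANKRD37 (2.64), the glucose transporter SLC2A3 (1.24) and STC2 (1.41); DDIT4 and STC2 belong to both lists. Immediate early genes had a median of 0.57 with 6 of 27 higher, including ATF3 (1.24), NR4A1 (1.48) and FOS (1.20). The heat shock list had a median of −0.55 but its members parted: 4 of 19 were lower, and HSPA6 (1.04) and the small heat shock protein gene CRYAB (2.11) were higher. Mitochondrially encoded genes had a median of −0.66 with 1 of 15 lower, MT-ATP8 (−1.06). Ribosome biogenesis (−0.34), cholesterol synthesis (−0.27) and HOX genes (−0.25) stood apart downward with no member passing the rule.

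Another 4 lists stood apart upward in C1233W: Notch targets (0.45, 1 of 18 higher, DLL4 at 1.49), cell adhesion (0.20, 1 of 31 higher, L1CAM at 1.16), DNA repair genes (0.04) and ribosomal proteins (−0.10). The last was above its expression-matched random lists but below the median of all genes, and the mean of the repair list, −0.01, had the opposite sign to its median. Altogether 878 genes passed the rule, 681 higher and 197 lower, or 943 and 125 on total-count scaling, where the all-gene median was 0.12. The repair call was lost under each of the 6 alternatives run for lists (percentiles 98.08 to 98.99), and the adhesion call without a filter (97.0), with the GC and length trend removed (98.6) and with a minimum of 5 CPM, where its median turned to −0.01. Removal of that trend also ended the Notch (97.2) and cholesterol (1.66) calls and left HSPA6 at 0.95 and MT-ATP8 at −0.71; on total counts MT-ATP8 was at −0.93.

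**Figure D2:**
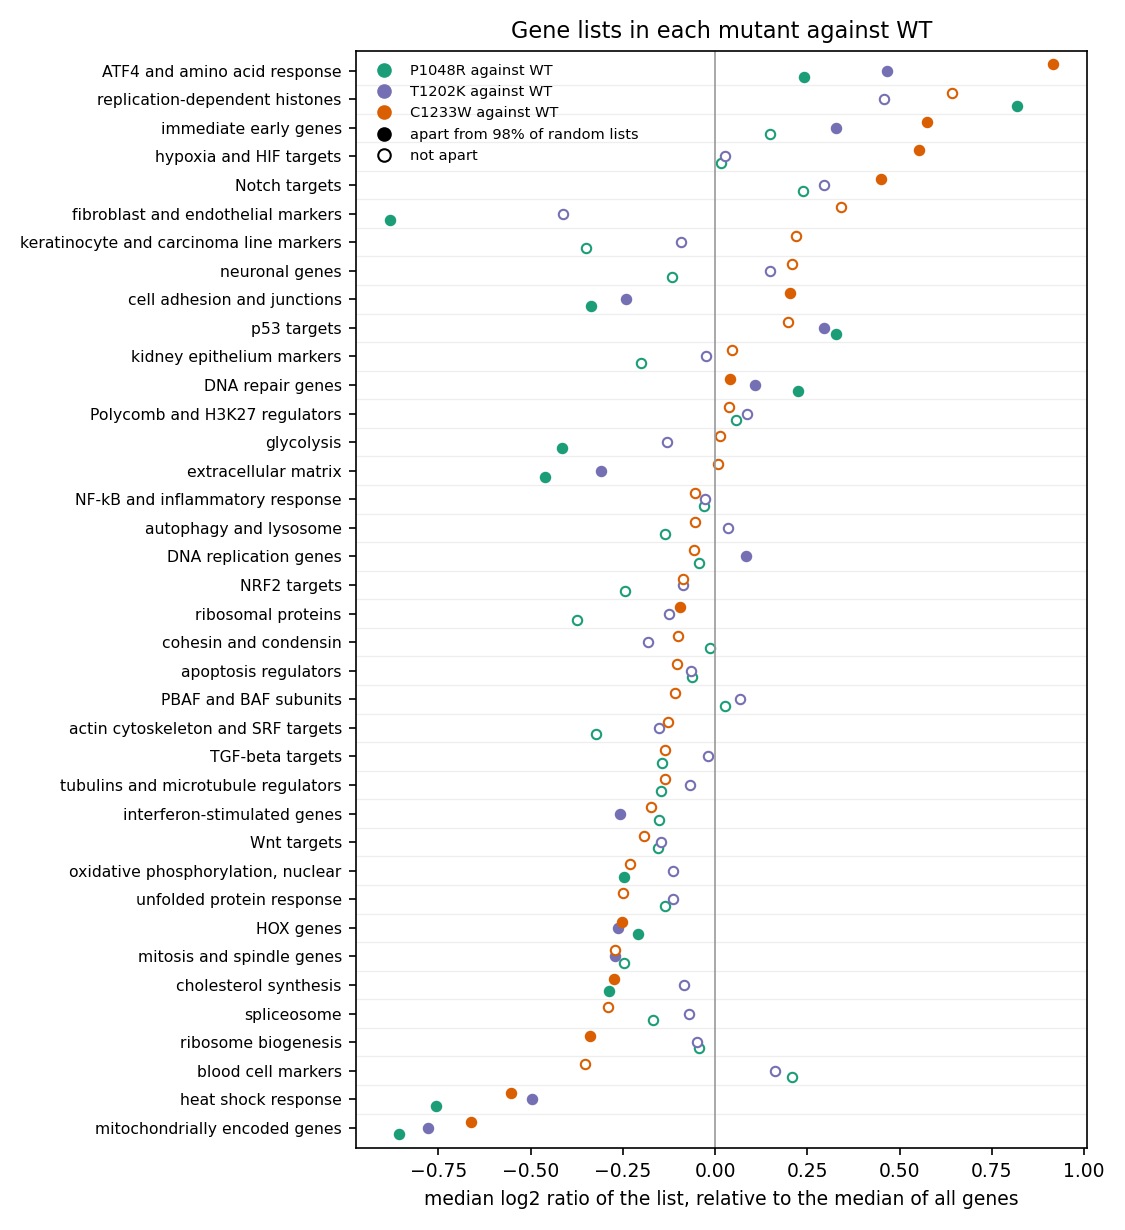
Median log2 ratio of each of the 38 gene lists, relative to the median of all genes, for P1048R (green), T1202K (purple) and C1233W (orange) against WT, 1 library each; filled points stood apart from matched random lists and open points did not. The ATF4 and amino acid response list reached 0.92 in C1233W against 0.24 in P1048R and 0.47 in T1202K, and mitochondrially encoded genes lay between −0.86 and −0.66 in all 3 mutants.

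In 258 genes WT stood apart from all 3 mutants, 54 higher and 204 lower in WT. PHF21B was at 9.09 CPM in WT and at 52.9, 39.0 and 35.2 in P1048R, T1202K and C1233W. The adhesion receptor gene ADGRB2 was at 14.7 CPM in WT and at 54.7, 41.3 and 48.4 in the mutants, and CCNB1IP1, a regulator of meiotic crossovers, at 44.5 against 122, 123 and 107. CDT1, RIMS2, CELSR3 and the oviductal glycoprotein gene OVGP1 were also lower in WT than in each mutant. HMGN5, at 229 CPM, and MT-ATP8, at 4142 CPM, were at least 2-fold higher in WT than in each mutant. So were the mitochondrial tRNA genes MT-TE (175 CPM against 54.9, 41.2 and 54.5) and MT-TL2, and pseudogenes such as HSP90AB2P, PTMAP4 and XRCC6P2, whose reads can come from their parent genes. With the GC and length trend removed, MT-ATP8 was under 2-fold in each mutant (−0.93, −0.94 and −0.71), MT-TL2 in C1233W (−0.92) and CDT1 in T1202K (0.93). On total counts, HMGN5 was under 2-fold in P1048R (−0.95) and MT-ATP8 in C1233W (−0.93).

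By biotype, 166 of the 204 genes lower in WT were protein coding, whereas 20 of the 54 higher in WT were processed pseudogenes and 9 were protein coding. Their median GC content was 53.2% for the lower and 43.9% for the higher genes, against 48.0% for all genes tested. Median transcript length was 2921 bp for the lower and 769.5 bp for the higher genes, against 3385 bp for all genes tested. Of the fixed lists, the ATF4 and amino acid response held 3 of the genes lower in WT, which were SLC7A11, TRIB3 and SLC3A2 (the last named after its values were seen), the Wnt target list held 2, NOTUM and SP5, and replication-dependent histones held 2, HIST1H4H and HIST2H4A. The replication gene CDT1, the autophagy regulator TFEB and the kidney marker CUBN were the single members of their lists lower in WT, and COL6A3 and MT-ATP8 of theirs higher in WT. SP5 in C1233W no longer passed with the GC and length trend removed (1.17, with an interval reaching 0), nor did COL6A3 in P1048R on total counts or with thinned counts. On total-count scaling the split of genes apart in WT was 22 higher and 330 lower.

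Fold changes of the mutants against WT resembled each other across genes, which are not independent replicates. Pearson's r was 0.80 between P1048R and T1202K, 0.64 between P1048R and C1233W and 0.63 between T1202K and C1233W, with covariances of 0.293, 0.238 and 0.212. Unchanged libraries sharing 1 control gave a simulated r of 0.546 with a covariance of 0.0540 from counting error, and 0.518 with 0.140 from the spread of all 4 libraries. Mean r was 0.69 with WT as the common reference, against 0.47 with P1048R, 0.30 with T1202K and 0.49 with C1233W. The last mean joined unlike values. With C1233W as reference, r was 0.71 between P1048R and T1202K (covariance 0.182). It was 0.33 between WT and P1048R and 0.44 between WT and T1202K. P1048R and T1202K shared 246 genes lower than in C1233W, where independent sets would share 18.5. Their resemblance was thus not limited to the WT reference. P1048R and T1202K shared 374 genes higher than in WT, where independent sets would share 21.4, and 170 lower, against 10.8. P1048R and C1233W shared 311 (30.5) and 82 (5.95), and T1202K and C1233W 235 (20.1) and 83 (4.35). Simulated unchanged libraries shared 8.67 genes per direction with counting error and 74.8 with the wider spread. They had 97.8 and 609 genes passing the size rule per mutant, and 6.29 and 63.7 genes apart in WT. The observed 201 and 575 genes between T1202K and the other mutants, and the 38 and 12 genes apart in P1048R and T1202K, lay below the wider-spread values. The wider spread holds any differences between the constructs themselves, so it is an upper limit. Counts below it are therefore not shown to lie within the spread between cultures of 1 construct. A single WT library cannot be split, so part of the excess may come from the shared control.

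Between mutants, T1202K and P1048R were the closest pair, with 201 genes passing the rule, 93 higher and 108 lower in T1202K. Ribosomal proteins (median 0.19), actin and SRF targets (0.20), glycolysis (0.29), the heat shock list (0.17), cholesterol synthesis (0.16) and nuclear oxidative phosphorylation (0.14) stood apart upward in T1202K with no member passing the rule. Tubulins and microtubule regulators (0.15) also did, with 1 member higher, MAP2 (1.15; not passing with thinned counts), and 1 lower. Extracellular matrix (0.13), fibroblast and endothelial markers (0.48), NRF2 targets (0.16) and Notch targets (0.16) also stood apart upward. Histones (−0.36), DNA repair (−0.10) and cohesin and condensin (−0.10) stood apart downward. Calls for NRF2, Notch, matrix, histone, cohesin, tubulin and fibroblast lists were each lost under at least 1 alternative, and the fibroblast median turned to 0.00 without a filter.

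C1233W differed from P1048R in 738 genes, 607 higher and 131 lower, and from T1202K in 575, 496 higher and 79 lower. The ATF4 and amino acid response list was higher in C1233W than in P1048R (median 0.65, 6 of 27 members higher) and T1202K (0.51, 5 higher), and so was the hypoxia list (0.64, 5 of 26 higher, and 0.55, 4 higher). SLC2A3 was higher by 2.39 (2.22 to 2.56) against P1048R and 1.78 (1.64 to 1.94) against T1202K, and HSPA6 by 3.11 (2.64 to 3.65) and 2.16 (1.79 to 2.56). Extracellular matrix (0.46 and 0.38), cell adhesion (0.37 and 0.27) and mitochondrially encoded genes (0.25 and 0.22) stood apart upward, and ribosome biogenesis downward (−0.26 and −0.30), against both. CDH1 was among the adhesion genes higher against both, by 1.54 and 1.26. The list of fibroblast and endothelial markers shares COL3A1, COL1A1 and LUM with the matrix list, so the 2 lists are not independent. Its median was 1.01 against P1048R, with 3 of 7 members higher, and 0.64 against T1202K, which did not stand apart. KDR and COL3A1 were at 3.68 and 11.1 CPM in C1233W. On total counts COL3A1 was under 2-fold against T1202K (0.996).

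Against P1048R, 8 further lists stood apart upward: glycolysis (0.35), neuronal genes (0.35), immediate early genes (0.34), kidney epithelium markers (0.43), ribosomal proteins (0.29), actin and SRF targets (0.25), NRF2 targets (0.23) and TGF-beta targets (0.17). Histones (−0.39) and DNA repair genes (−0.17) stood apart downward. Against T1202K the spliceosome list (−0.16) did so. The calls for kidney, TGF-beta, histone and immediate early genes, and for mitochondrial genes against P1048R, were lost under at least 1 alternative.

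In 105 genes C1233W stood apart from all 3 other libraries, 95 higher and 10 lower. They included SLC7A11, DDIT4, ASNS, CHAC1, JDP2, IL11, ANKRD37, SLC2A3, HSPA6, CRYAB, L1CAM and the podocyte gene SYNPO on the higher side, and HSPA1A on the lower. Of these, L1CAM was at 0.98 against P1048R on total counts and HSPA6 at 0.95 against WT with the GC and length trend removed, so that neither stood apart there. P1048R stood apart in 38 genes, 13 higher and 25 lower, with COL5A3 and the ETS factor gene ETV2 among the higher; T1202K did so in 12, 2 higher and 10 lower. The 2 were the pseudogenes LPAL2 and NDUFV2P1, named after their values were seen. On total-count scaling the splits were 19 and 15 for P1048R and 3 and 6 for T1202K. Without the WT library, 63, 42 and 278 genes stood apart in P1048R, T1202K and C1233W.

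**Figure D3:**
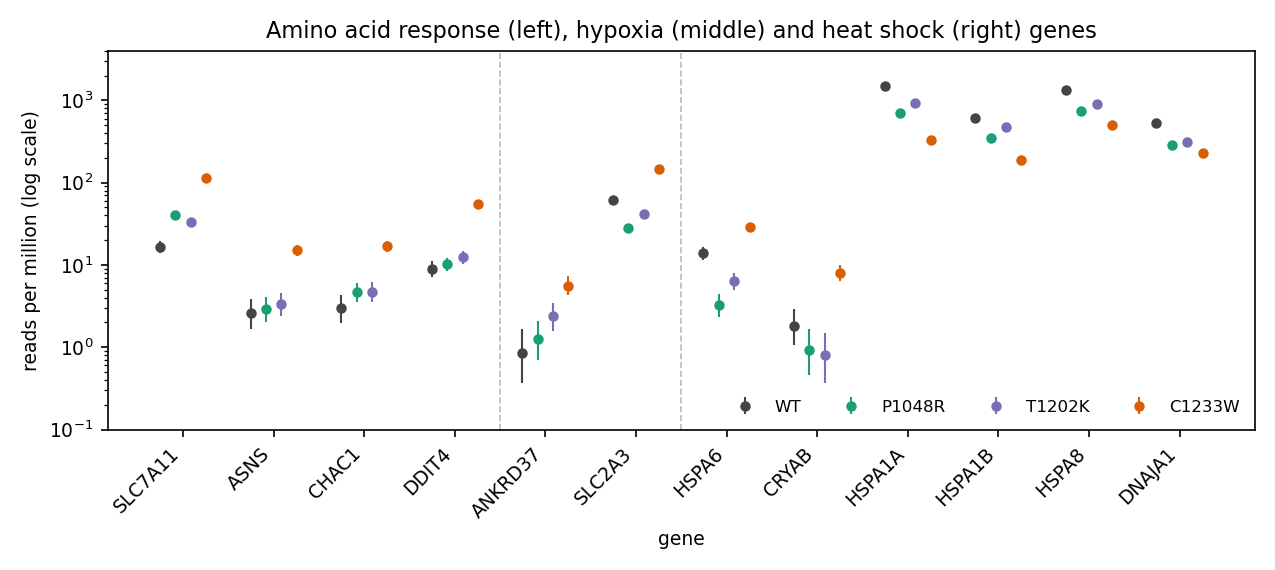
CPM (log scale, TMM-scaled) of amino acid response, hypoxia and heat shock genes in each library, with exact 95% Poisson intervals that cover counting error only. C1233W (orange) lay above the other 3 libraries for SLC7A11, at 112 against 16.5 to 40.7, and below them for HSPA1A, at 328 against 697 to 1474.

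Several fixed lists stood apart in none of the 6 comparisons at the settings used throughout. Against WT, PBAF and BAF subunits had medians of 0.03, 0.07 and −0.11 in P1048R, T1202K and C1233W, with 3 of 27 members higher in P1048R and 2 in T1202K. These were BICRAL, a subunit of the non-canonical BAF complex (1.34 and 1.04), the neuronal subunit gene ACTL6B, with 1 read in WT (2.59, 0.32 to 8.53, and 3.09, 0.93 to 9.03), and, in P1048R, SMARCD3, at 45.7 CPM against 22.8. Polycomb and H3K27 regulators lay at 0.06, 0.09 and 0.04, with PHF1 at 1.04 in P1048R. The unfolded protein response lay at −0.14, −0.12 and −0.25, with HSPA5 at −1.02 in P1048R (−0.97 with DESeq2 size factors, −0.79 on total counts and −0.98 with the GC and length trend removed), DDIT3 at 1.05 in C1233W and TRIB3 above 2-fold in each mutant. Wnt targets lay at −0.16, −0.15 and −0.19, with NOTUM and SP5 above 2-fold in each mutant and WIF1 at −1.62 in P1048R.

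The NF-kB list lay at −0.03, −0.03 and −0.05, with RELB higher (1.88) and IER3 (−1.07) and BIRC3 (−1.08) lower in P1048R. With a minimum of 5 CPM its median in P1048R turned to 0.64 and stood apart (percentile 99.01). Apoptosis regulators lay at −0.06, −0.07 and −0.10, with BIRC3 lower in P1048R and HRK (1.27) and BBC3 (1.10) higher in C1233W, and autophagy and lysosome at −0.14, 0.03 and −0.06, with TFEB higher in each mutant. Metallothioneins (−0.12, 0.14 and −0.15) and small nuclear and structural RNAs (−0.76 in P1048R and −0.54 in C1233W, and lower still in T1202K, where MALAT1 and NEAT1 passed the rule), each with 4 members measured, were too few for a percentile. Markers of blood cells, 5 measured, lay at 0.21, 0.16 and −0.35, with CD4 lower in T1202K (−1.62) and LCP1 (1.08) and CORO1A (1.13) higher in C1233W. Those of keratinocytes and carcinoma lines, 6 measured, lay at −0.35, −0.09 and 0.22, with ALB, at 2 reads in WT, higher in P1048R (2.53, 0.75 to 5.97) and C1233W (2.74, 0.96 to 6.18). The calls for ACTL6B, SMARCD3, PHF1, IER3 and BIRC3 in P1048R and for SP5, BBC3, LCP1 and CORO1A in C1233W were each lost under at least 1 alternative. Some of these lists stood apart between mutants under an alternative. In C1233W against P1048R these were PBAF and BAF subunits with the GC and length trend removed (percentile 0.94), autophagy with it removed (99.44) and with a minimum of 5 CPM (99.2), and keratinocyte markers without a filter (99.42); in T1202K against P1048R, apoptosis regulators did so without a filter (99.9).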

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

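The alternatives with the GC and length trend removed, with PBRM1 and mitochondrial genes left out of the scaling, with PBRM1 left out of the totals and without the WT library were chosen after the data were seen. With 1 library per construct, genes near 1 CPM rest on about 10 reads, and differences near 2-fold in them were mostly within counting error. Counts of genes with both directions added stayed within 1.5 times under DESeq2 size factors, total counts, no filter and thinning. The same held for the GC and length correction and the scaling without PBRM1 and mitochondrial genes. Counts of 1 direction did not all do so. On total counts, genes higher in P1048R than in WT went from 728 to 1253, and those lower from 491 to 231. For T1202K against WT, higher genes went from 479 to 806 and lower genes from 359 to 221. Genes higher in WT alone went from 54 to 22. Of the 258 genes apart in WT, 193 stayed so among 220 after the GC and length correction, as did 98 of 105 for C1233W.

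The remaining settings moved the counts by their own construction, since they change the threshold, the genes tested, the libraries compared or the test itself. In the order P1048R, T1202K and C1233W against WT, T1202K and C1233W against P1048R, and C1233W against T1202K, a 1.5-fold threshold gave 3197, 2156, 2229, 545, 1787 and 1442 genes. A minimum of 5 CPM gave 603, 359, 330, 17, 201 and 124, and a counting bound of at least 1.5-fold gave 652, 394, 366, 23, 264 and 177. For genes apart in WT, P1048R, T1202K and C1233W alone, the 1.5-fold threshold gave 807, 155, 33 and 315, the 5 CPM minimum 136, 6, 2 and 30, and the bound 111, 2, 1 and 32. Leaving out WT gave 63 for P1048R, 42 for T1202K and 278 for C1233W. WT had the highest such number of the 4 libraries under each size rule that kept all 4. The edgeR quasi-likelihood fit of 1 library against the other 3 called 454, 0, 0 and 1 genes at an adjusted p of 0.05 in the same order of libraries (2951, 548, 82 and 676 at an unadjusted p under 0.05). Its single arm has no spread, its other arm mixes 3 constructs and, for a mutant, includes WT, so these counts say nothing on the stability of the others.

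Correlations of the mutant ratios (P1048R with T1202K, P1048R with C1233W, T1202K with C1233W) were 0.879, 0.698 and 0.688 with a minimum of 5 CPM and 0.591, 0.533 and 0.541 without a filter, which adds genes of few reads. PBRM1 was at 22442 CPM in WT and 8936 in P1048R with DESeq2 size factors, and at 20768, 9381 and 15721 in WT, P1048R and T1202K on total counts; the order of the 4 libraries did not change. Of 228 list medians, 206 kept their side of the threshold with the GC and length trend removed, 12 were no longer apart and 10 newly were; 224 kept it with DESeq2 size factors and 223 on total counts. Of the calls lost, 2 came with a median that reversed: cell adhesion in C1233W against WT, −0.0117 with a minimum of 5 CPM, and fibroblast and endothelial markers in T1202K against P1048R, 0.00 without a filter. Another 2 lists newly stood apart with a changed sign: the NF-kB list in P1048R against WT, 0.64 with a minimum of 5 CPM, and ribosomal proteins in C1233W against T1202K, −0.07 without a filter. Ribosomal proteins in C1233W against WT kept their call without a filter at 0.01, and many medians near 0 that stood apart in neither setting also changed sign; the cause was not tested. The GC and length correction took 32 of the named genes' 2-fold differences below the rule, among them MT-ATP8 (−0.93, −0.94 and −0.71 in P1048R, T1202K and C1233W), and total-count scaling took 36.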

Other observations

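The weighing of patterns below includes tests chosen only after the results were seen: the rank of WT by PBRM1 level, the amino acid response over all 4 libraries, the share of reads taken by PBRM1, both tests of genes of low expression, the correction for GC content and length, and the totals without PBRM1.

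Mitochondrial transcripts did not shift as a block. Messenger RNAs were lower in the mutants, MT-ND6 at 2054, 2053 and 2909 CPM in P1048R, T1202K and C1233W against 4866 in WT, and MT-ND2 at 2519, 2644 and 3037 against 5764. The small ribosomal RNA, MT-RNR1, was higher in the mutants, at 1458, 1374 and 1568 CPM against 902, and the large one, MT-RNR2, lay between 6457 and 6952 CPM in all 4 libraries. MT-CO1, at −0.39, −0.30 and −0.10 on the log2 scale (0.03 in C1233W on total counts), differed least among the messenger RNAs with TMM scaling. These 3 genes were chosen after their values were seen. With the GC and length trend removed, MT-ND4L differed less than MT-CO1 in P1048R (−0.18 against −0.35) and T1202K (−0.19 against −0.26), as did MT-ND3 in T1202K (−0.21). In C1233W only MT-ATP8 of the 15 members passed the size rule; MT-ND6 no longer passed in P1048R and T1202K with the GC and length trend removed, nor MT-ND2 in both on total counts (−0.97 and −0.95) and in T1202K with that trend removed (−0.98). Mitochondrial genes took 8.48% of counted reads in WT and 5.63%, 5.53% and 6.23% in the mutants. The nuclear long non-coding RNAs also parted in C1233W, where MALAT1 was at −0.73 and NEAT1 at 0.11 against WT, while against T1202K both were higher, by 1.12 and 1.44.

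Host genes of small nucleolar RNAs, 24 measured, had medians of 0.39, 0.18 and 0.27 in P1048R, T1202K and C1233W against WT, with 4, 4 and 0 members higher by the size rule and 0, 1 and 0 lower. Decay factors of the UPF and SMG families, 10 measured, had medians of 0.21, 0.01 and 0.01 with none passing the rule. Olfactory receptor genes, silent in most tissues, held 61, 56, 47 and 77 reads over 381 genes in WT, P1048R, T1202K and C1233W.

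The WT library stood apart from all others in 258 genes, against at most 105 for a mutant library. GC content and transcript length did not account for most of it. After both trends were removed, 220 genes stood apart in WT, against 107 for the highest mutant. A response graded by PBRM1 transcript would not single out WT, which ranked 2 of the 4 by PBRM1 transcript level. Protein was not measured, so a response graded by PBRM1 protein was not tested. Loss of BAH domain function in all 3 mutants remains a hypothesis that cannot be told apart from a property of the culture or library, because there was 1 WT library. Less nonsense-mediated decay in the mutants was a further candidate explanation, as host genes of small nucleolar RNAs are decay targets. It predicted that their percentile would exceed 99 in each mutant. The lowest of the 3, in T1202K, was 96.87, so the prediction set beforehand was not met. With the GC and length trend removed, a correction chosen after the data were seen, the lowest percentile was 99.83. Of the 24 host genes measured, 0 passed the size rule in C1233W against WT, so none is among the 258. Their medians thus cannot say whether less decay accounts for those genes, and the question stays open.

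The amino acid response list had a higher median in C1233W than in the other 3 libraries, though only 4 of its 27 members stood apart there and others, such as ATF3 (199 CPM against 232 in P1048R) and WARS (lowest in C1233W; both chosen after their values were seen), did not follow; C1233W also had the most PBRM1 reads. T1202K held less PBRM1 transcript than WT. A response graded by that transcript over all 4 libraries would therefore place the list lower in T1202K. The list's median was instead 0.466 in T1202K over WT (bootstrap interval over members 0.258 to 0.658, and 0.375 with the GC and length trend removed). The interval holds no spread between cultures and the comparison rests on 1 WT library, so a graded response is not excluded. The share of reads taken by PBRM1 moves all other genes of a library alike and, being largest in C1233W, lowers them there. Not taken relative to all genes, the list median in C1233W over T1202K was 0.441 on total counts and 0.508 without PBRM1 in the totals. By construction, that share leaves a median relative to all genes unchanged. The relative median of 0.505 (0.275 to 0.753) could therefore not come from that share, whatever its value. A graded response among the mutants alone cannot be told apart from none, with a median of 0.0662 in T1202K over P1048R and an interval of −0.0983 to 0.153. An effect of the C1233W change itself, or of how that culture was transfected, may also contribute and was not tested, as 1 library holds both.

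Genes of low expression were mostly higher in C1233W: under a mean of 2 CPM, 316, 333 and 274 genes passed the size rule upward against T1202K, P1048R and WT, and 43, 74 and 124 downward, while T1202K and P1048R themselves lay low against WT (medians −0.17 and −0.15). Genes with a mean of at least 20 CPM lay slightly low in C1233W, with median log2 ratios of −0.085, −0.066 and −0.092 against T1202K, P1048R and WT. Among genes with at least 1 CPM in 1 of the 2 libraries not compared and a mean of these 2 under 5 CPM, 64.2% of 4022 were higher in C1233W than in P1048R (62.7 to 65.7), 65.7% of 4117 than in T1202K and 60.6% of 3814 than in WT, above the 51.4%, 51.9% and 52.1% that were the highest of 100 simulations with counting error alone. Reads spread evenly over the genome, as from residual DNA, were weighed with olfactory receptor genes, at 7.45 CPM in C1233W (5.88 to 9.31) against 4.69 in P1048R and 4.15 in T1202K. The largest even background they allow would raise genes under 2 CPM, picked in the same way, by 0.0147 CPM, against observed median rises of 0.207 CPM over P1048R (0.169 to 0.233) and 0.234 over T1202K. No biological explanation was tested for this pattern, and whether it belongs to the construct or to that 1 library is open.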
